A study of Homo sapiens with 7 samples.

How the data were processed

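Total RNA sequencing was deposited for 7 libraries of 2 human T-ALL cell lines. PF-382 had 2 wild-type and 3 STAG2 knockout libraries, and MOLT-14 had 1 empty-vector and 1 STAG2-transduced library. The processing notes name STAR and RSEM and the builds GRCh38 and hg38, without versions, and give neither the annotation release nor the strand setting. Each deposited file held 60754 features with expected counts (estimated reads per gene, not normalised, per the file headers). The authors also gave TPM (transcripts scaled to a fixed sum per library) in the same files. The authors further gave FPKM (fragments scaled by gene length and library) there. The expected counts were used here, TPM only for a comparison of implied gene lengths, and FPKM not at all. The 92 ERCC spike-in features were left out, which held 3 counts in the STAG2-transduced library and 0 in the others. Gene positions, exonic lengths and GC content came from GENCODE 29 (GRCh38), which held 58587 of the 60662 genes.

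Expected counts were rounded to whole numbers, and 91.8% to 93.3% of them were whole already. Genes with fractional counts in any library share reads with other genes, and 1368 of the called genes were of this kind. The PF-382 libraries were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr on the group, quasi-likelihood test, two-sided). P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all adjusted p values for single genes are of this kind unless another tool is named. Only PF-382 libraries entered this fit, since the MOLT-14 groups have 1 library each. The biological coefficient of variation was 0.242. Log2 changes are knockout over wild type, and CPM values use TMM-scaled totals. The standard errors of log2 changes were derived from the log2 change and edgeR's F statistic, since the test gives none. In simulated data with the same design, 31% of genes changed 2-fold and 66% of genes changed 4-fold were called in their direction, and 6.73% of the calls were unchanged genes. With no gene changed 0 calls were made. The simulation changed a far smaller share of the genes than the 30.4% called here, and it gave both groups the same spread. Its shares need not hold for these data.

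Gene lists were fixed before the data were examined: 28 lists of cohesin, T-ALL oncogene, HOXA, stem cell, T-cell receptor, thymocyte, gamma delta, Notch, homologous recombination, end joining, DNA replication, mitotic, p53, interferon, MHC, JAK-STAT, BCL2, protocadherin, immediate early, ribosome biogenesis, glycolysis and hypoxia, sterol, and amino acid response genes, and markers of 5 other cell types (B-lineage, myeloid, natural killer, erythroid and megakaryocyte, stromal and epithelial). They were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether genes of a list move and does not compare it with other genes, were run beside it. With an estimated correlation, camera takes its degrees of freedom from the few libraries. It has little power here, and a lost call does not show correlation alone. Fry called 11 lists in 1 direction and 24 in either direction. In 1 direction it did not call the homologous recombination (adjusted p 0.0865) and mitotic lists (0.420), which camera called. The mitotic list was not called in either direction (0.149). Fry called lists that camera did not: T-ALL oncogenes, stem genes, and myeloid and stromal markers, all lower (0.0324 each), and end joining genes, higher (0.0479). A further 7 lists were chosen after seeing the data and are reported apart.

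MOLT-14 was compared by the log2 ratio of TMM-scaled CPM with a prior count of 2, among genes with at least 5 CPM in either library. Intervals of single ratios are exact binomial intervals at 95%, and like the floors of 3 counts they cover counting error only, since reads without molecular identifiers are not independent molecules. List medians were set against 10000 random lists matched on expression in 20 bins. The comparison of lines used genes called in PF-382 with at least 1 CPM in either MOLT-14 library and exact Clopper-Pearson intervals. The shared fit used all 7 libraries with the cell line as an additive term. In simulated data for that fit 57.5% of genes changed 4-fold were called, and 4.17% of the calls were unchanged genes. That simulation too changed a small share of the genes and gave all groups the same spread, so these shares need not hold here.

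Depth was 32609485 to 93970572 counts in PF-382 and 38678382 to 45013453 in MOLT-14, so that 3 counts make 0.0319 to 0.0920 CPM. Named genes followed a rule fixed before the data were examined. For PF-382 it took every detected cohesin gene, the 12 largest folds each way among protein-coding called genes of at least 1 CPM with groups that do not overlap, and from each list the members with the smallest adjusted p, of which the first 1 to 4 are printed. For MOLT-14 it took STAG2, the 10 largest ratios each way among protein-coding genes, and the genes of the largest folds in PF-382, of which those with the most counts or a ratio past 2 are printed. For both lines it took the 10 genes with the smallest adjusted p at least 2-fold the opposite way. LMO2 was named in every comparison. Some genes that the rule takes are not reported here. RAG1, RAG2, T-cell receptor segments and the genes of the 7 added lists were chosen after their values were seen.

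Alternatives were DESeq2's size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0 (Wald test), limma voom, robust dispersion, other filters, unrounded counts, each library left out in turn, all 7 libraries in 1 fit, and subsets by the SA and SB prefixes of the titles, whose meaning the labels do not give. Chosen after seeing the data were thinning of the libraries to the smallest total, protein-coding genes only, and removal of each library's trend on GC content and length. With 2 wild-type libraries, splits of the samples into other groups were not run, and a left-out wild-type library leaves 1 that is assumed to vary like the knockout group.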

Results

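RNA was sequenced from total RNA libraries of 2 human T-cell acute lymphoblastic leukaemia (T-ALL) cell lines in which the level of STAG2, a subunit of the cohesin ring that holds and loops DNA, had been altered. In PF-382, 3 libraries came from cells whose STAG2 gene was knocked out by delivery of Cas9 and guide RNA as a ribonucleoprotein, and 2 came from wild-type cells. In MOLT-14, 1 library came from cells transduced with STAG2 and 1 from cells transduced with an empty vector. The total counts were 32609485 and 33145516 in the wild-type PF-382 libraries and 65262329, 93970572 and 81304948 in the knockout libraries. The MOLT-14 libraries held 38678382 counts with the empty vector and 45013453 with STAG2. Small RNA genes here are snRNA, snoRNA, scaRNA, ribozyme and miscellaneous RNA genes, without microRNAs. They took 21.0% and 14.9% of the counts in the wild-type PF-382 libraries and 11.96%, 13.98% and 13.7% in the knockout libraries. Pearson's r of log CPM (counts scaled to a common library total), across genes, was 0.962 between the wild-type libraries, 0.985 to 0.989 between the knockout libraries and 0.944 to 0.947 between the groups.

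The comparison in PF-382 asks which genes change when STAG2 is inactivated. STAG2 RNA fell and its paralogue STAG1, the alternative subunit of the cohesin ring, rose. STAG2 (ENSG00000101972.18, GRCh38 chromosome X, 123960212 to 124422664) had 426 ± 157 CPM (SD, n = 2) in wild type and 195 ± 38.3 CPM (SD, n = 3) in knockout, a log2 change of -1.13 ± 0.26 (SE) with an adjusted p of 0.0218. STAG1 (ENSG00000118007.13, chromosome 3, 136336233 to 136752403) had 50.3 ± 4.31 CPM (SD, n = 2) in wild type and 129 ± 1.37 CPM (SD, n = 3) in knockout, a log2 change of 1.36 ± 0.11 (SE) with an adjusted p of 0.00222. RAD21, the kleisin subunit of the ring, fell from 1009 ± 101 to 548 ± 16.9 CPM (SD, n = 2 and 3, log2 change -0.88, adjusted p 0.00628), and ESCO2, an acetyltransferase that acts on cohesin, rose from 61.7 ± 5.11 to 109 ± 9.60 CPM (log2 change 0.82, adjusted p 0.00715). The meiotic subunits SMC1B and REC8 changed by -3.00 and 0.44 on the log2 scale (adjusted p 0.0359 and 0.0453). Of the 22 cohesin genes tested, 3 rose, 3 fell and 16 did not pass, and adjusted over the list alone the counts were also 3 and 3. The log2 changes of those 16 genes (MAU2, ESCO1, HDAC8, ESPL1, PTTG1, SGO2, NIPBL, SGO1, CTCF, PDS5A, STAG3, SMC1A, WAPL, CDCA5, SMC3 and PDS5B) lay between -0.54 for PTTG1 and 0.36 for HDAC8. The STAG2 call was lost without knockout 2 (log2 change -1.03, adjusted p 0.0757) and without knockout 3 (-1.09, 0.0773), and the change was -0.67 without wild type 2. SMC1B was lost without wild type 1, knockout 1 or knockout 3 (adjusted p 0.159, 0.100 and 0.102), and REC8 without wild type 1 or any knockout library (0.0585, 0.0945, 0.152 and 0.0994).

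**Figure D1:**
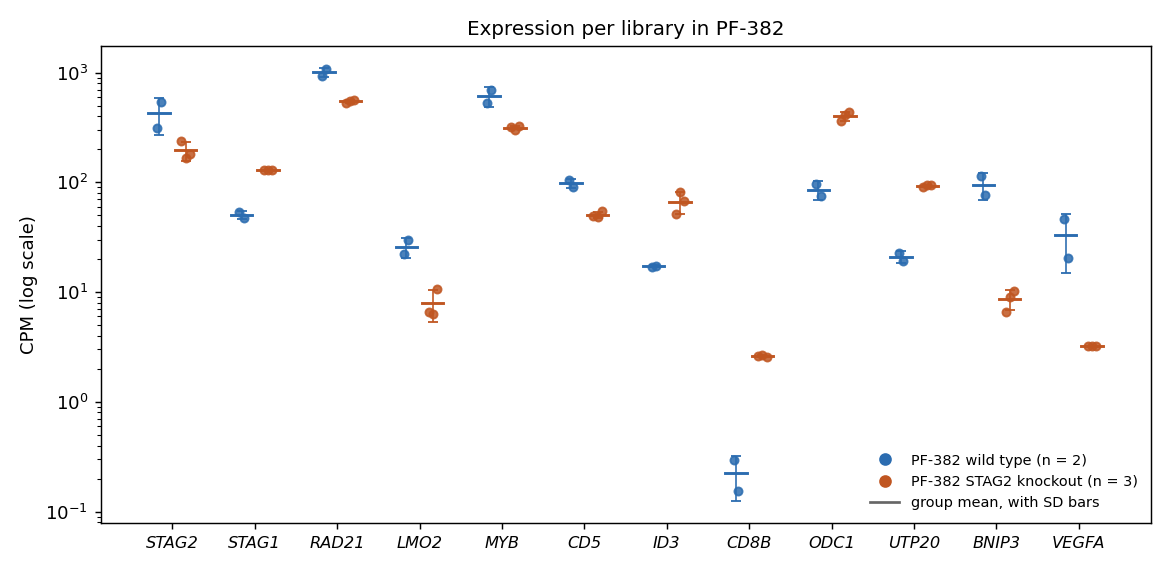
CPM on a log axis for 12 genes in the 2 wild-type and 3 knockout PF-382 libraries, 1 point per library, with the group mean as a line and the SD as bars. STAG2 averaged 426 CPM in wild type and 195 CPM in knockout, and STAG1 averaged 50.3 and 129 CPM.

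Across the transcriptome, 5311 of the 17442 genes tested in PF-382 changed, 2763 higher and 2548 lower in knockout (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, two-sided). By at least 2-fold, 929 genes were higher and 1770 lower. Among protein-coding genes, 2591 rose and 1620 fell, while a fit of protein-coding genes only called 2046 higher and 1938 lower. With upper-quartile scaling, which moved the median log2 change of all genes from -0.02 to -0.18, 1824 genes were higher and 3566 lower, so that 33.8% of the calls were higher instead of 52.0%. The groups did not overlap for 59.8% of the genes, where chance gives 20%. The count was 2649 without knockout 1, 2344 without knockout 2 and 2271 without knockout 3. Nothing in the labels says that libraries of 1 group are separate cultures, so each p measures the spread between these libraries, and the deeper libraries are all knockout. The fit assumes 1 spread per gene for both groups. Pearson's r was 0.962 between the wild-type libraries and 0.985 to 0.989 between the knockout libraries. Where the wild-type libraries disagree, p may therefore be too small.

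The largest rises included a T-cell coreceptor gene and a purinergic receptor gene. CD8B, a chain of the CD8 coreceptor, rose 11.6-fold from 0.224 ± 0.0997 CPM (SD, n = 2) to 2.62 ± 0.0417 CPM (SD, n = 3, adjusted p 0.00317), and ADORA2A, an adenosine receptor, rose 10.8-fold to 9.75 ± 2.40 CPM. GPRIN1 rose 12.9-fold to 10.6 CPM and METTL7A 12.4-fold to 16.0 CPM. Without wild type 1 the log2 changes were 4.74 instead of 3.69 for GPRIN1, 3.04 instead of 3.64 for METTL7A and 4.07 instead of 3.44 for ADORA2A, and without wild type 2 that of METTL7A was 4.72. CRISPLD1 rose from 0.0908 to 3.43 CPM and ZNF697 from 0.148 to 1.72 CPM, from wild-type levels near the 0.0905 to 0.0920 CPM of 3 counts. The log2 change of ZNF697 was 4.78 without wild type 1 and 2.89 without wild type 2 instead of 3.51, and that of CRISPLD1 5.84 without wild type 2 instead of 5.22. TMEM189-UBE2V1, an annotated readthrough gene that shares reads with its neighbours, had 0 counts in both wild-type libraries and 2.74 CPM in knockout, at least 30.4-fold higher against a floor of 3 counts per library. CTBP2 (0.106 to 6.43 CPM), ZIK1 (0.134 to 4.93), SH3TC1 (8.55 to 100.2) and PKP1 (0.281 to 3.17) rose as well, each with a call lost in 3 or 4 of the 5 fits that left out 1 library. CTBP2 was lost without wild type 1, wild type 2 or knockout 1 (adjusted p 0.0633, 0.0586 and 0.0553, with log2 changes of 5.70, 6.18 and 5.84 against 5.90) and ZIK1 without these or knockout 2 (0.0805, 0.113, 0.0809 and 0.0796, with 6.29, 4.59, 4.12 and 5.25 against 5.17). SH3TC1 was lost without knockout 1, 2 or 3 (0.0876, 0.0844 and 0.0792, with 3.45, 3.46 and 3.71 against 3.55) and PKP1 without wild type 2 or any knockout library (0.0685, 0.0594, 0.0785 and 0.0678, with 2.69, 3.76, 2.64 and 3.74 against 3.48). Log2 changes moved by over 1.5 times for SH3TC1 without wild type 2 (3.55 to 6.62) and for PKP1 without wild type 1 (3.48 to 5.67).

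The largest falls included stress-inducible, myeloid and B-cell genes. HSPA6, a heat-inducible HSP70 chaperone, fell from 119 ± 55.5 CPM (SD, n = 2) to 0.191 ± 0.0904 CPM (SD, n = 3, adjusted p 0.00218), 625-fold lower (log2 change -9.29, and -8.69 without wild type 2). CD68, a macrophage marker, fell from 7.29 ± 0.447 to 0.0904 ± 0.0364 CPM, and CTSG, a granule protease of myeloid cells, from 13.3 ± 12.3 to 0.0911 ± 0.0858 CPM. The log2 change of CTSG, -7.14, moved most without wild type 1 (-5.59), wild type 2 or knockout 3 (-8.20). BLNK, the B-cell linker protein, fell from 2.59 ± 0.541 to 0.0200 ± 0.0106 CPM, below the 0.0319 to 0.0460 CPM that 3 counts make in the knockout libraries. BHLHE40 (5.40 to 0.0271 CPM), ADM (2.504 to 0.0331) and MT1H (12.4 to 0.00777) also fell to levels around or under those of 3 counts. DSCAML1 fell from 8.81 to 0.193 CPM, RAB34 from 11.6 to 0.255, C16orf74 from 6.11 to 0.0886 and ANXA3 from 5.52 to 0.109. Log2 changes were -4.87 without wild type 1 and -6.44 without knockout 1 for RAB34 (instead of -5.53), and -4.63 and -4.07 without wild type 1 and -6.67 and -6.31 without wild type 2 for C16orf74 and ANXA3 (instead of -6.01 and -5.61). SYNM fell from 4.60 to 0.0528 CPM, a call that was lost without knockout 1, 2 or 3 (adjusted p 0.0570, 0.0516 and 0.0622). Without wild type 2 the log2 change of SYNM was -2.65 instead of -6.36 and that of MT1H -6.56 instead of -10.21. In each of these genes of the largest rises and falls all 3 knockout libraries lay on the same side of both wild-type libraries, as the choice of genes required.

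LMO2 and MYB, transcription regulators that act as oncogenes in T-ALL, fell in knockout. LMO2, a LIM-only cofactor (ENSG00000135363.12, chromosome 11, 33858576 to 33892289), fell from 25.9 ± 5.37 CPM (SD, n = 2) to 7.88 ± 2.499 CPM (SD, n = 3), a log2 change of -1.72 ± 0.27 (SE) with an adjusted p of 0.00760. MYB fell from 611 ± 121 to 316 ± 12.6 CPM (log2 change -0.95, adjusted p 0.00780). HHEX fell from 7.50 ± 6.28 to 0.164 ± 0.178 CPM (adjusted p 0.00931), with log2 changes from -6.78 to -4.17 when 1 library was left out. TLX2 fell from 4.01 ± 4.28 to 0.742 ± 0.0497 CPM (adjusted p 0.0432). Of the 9 T-ALL oncogenes tested, 4 fell and 5 did not pass (4 adjusted over the list alone), and the list was not called (camera adjusted p 0.0542, 0.769 with an estimated correlation, median log2 change -1.20). The TLX2 call was lost without wild type 1 (log2 change -0.39, adjusted p 0.420) and without knockout 1, 2 or 3 (0.112, 0.116 and 0.127). Of 20 stem and progenitor genes 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p 0.385). Besides LMO2 they included ERG, which fell from 29.7 to 4.65 CPM and was lost without wild type 2, knockout 1 or knockout 2 (adjusted p 0.0692, 0.0681 and 0.0715), with a log2 change of -1.57 instead of -2.68 without wild type 2. None of 5 HOXA genes tested was called (0 adjusted over the list alone; camera adjusted p 0.544). HOXA13 had 0.332 CPM in wild type and 0.0940 in knockout (adjusted p 0.0673), and HOXA3 had 0.328 and 0.595 CPM (adjusted p 0.170).

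Genes of T-cell differentiation moved both ways, as did the genes tested as a whole, of which 30.4% were called (52.0% of the calls higher). In the T-cell receptor and CD3 list of 30 genes 3 rose and 3 fell (1 and 2 adjusted over the list alone; camera adjusted p 0.544). CD8B rose, while CD5, which tunes receptor signals, fell from 98.3 ± 10.0 to 50.7 ± 3.09 CPM (SD, n = 2 and 3, adjusted p 0.00410) and NFATC1 from 33.9 ± 3.26 to 15.4 ± 2.93 CPM (adjusted p 0.00708). Of 33 thymocyte development genes 6 rose and 7 fell (7 and 10 adjusted over the list alone; camera adjusted p 0.544). ID3, an inhibitor of E proteins, rose from 17.1 ± 0.351 to 66.7 ± 14.9 CPM (adjusted p 0.00325) and CCR9, a thymic homing receptor, from 135 ± 23.4 to 323 ± 37.3 CPM (adjusted p 0.00532). Of 12 gamma delta T-cell genes, which share ID3 with the thymocyte list, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p 0.501), the latter ETV5, from 132 ± 1.96 to 20.9 ± 12.4 CPM (adjusted p 0.00895). Of 26 Notch genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p 0.9004). TRIB2 rose from 24.2 to 70.0 CPM (adjusted p 0.00599), and SHQ1 rose from 69.0 to 154 CPM with a call lost without knockout 1 or 2 (adjusted p 0.0531 and 0.0555). The thymocyte and Notch lists had positive means (0.12 and 0.08) with negative medians (-0.31 and -0.09) and a downward test.

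Most ribosome biogenesis genes tested and 21 of 42 DNA replication genes rose in knockout. Of 33 ribosome biogenesis and MYC target genes 28 rose and 2 fell (30 and 2 adjusted over the list alone), with a median log2 change of 1.16 and a camera adjusted p of 1.1e-11 (adjusted p 0.769 with an estimated correlation). UTP20, a nucleolar processome protein, rose from 21.1 ± 2.49 to 93.4 ± 1.83 CPM (SD, n = 2 and 3), NOP56, a box C/D snoRNP protein, from 124 ± 6.02 to 361 ± 5.99, NHP2 from 43.8 ± 1.92 to 121 ± 2.57, and ODC1, the first enzyme of polyamine synthesis, from 86.0 ± 16.2 to 401 ± 36.1 CPM (adjusted p 0.00218 each). Of 42 DNA replication genes 21 rose and 1 fell (27 and 2 adjusted over the list alone), with a median of 0.73 and a camera adjusted p of 6.61e-06 (adjusted p 0.781 with an estimated correlation). POLD2 rose from 96.1 ± 0.170 to 235 ± 10.6 CPM, POLA2 from 27.6 ± 2.25 to 63.8 ± 2.58, CDC45, a helicase subunit, from 35.8 ± 0.449 to 75.9 ± 4.16 and GINS4 from 17.5 ± 2.51 to 42.2 ± 3.74 CPM (adjusted p 0.00264 to 0.00378). Of 42 homologous recombination and Fanconi anaemia genes 9 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.32 and a camera adjusted p of 0.0179 (adjusted p 0.781 with an estimated correlation). ATR, a replication checkpoint kinase, rose from 59.5 to 107 CPM, FANCC from 9.47 to 22.02 and NBN from 69.9 to 115 CPM (adjusted p 0.00610 to 0.00824). The last list was no longer called without wild type 1 (adjusted p 0.274) or with a minimum of 1 CPM (0.109).

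Of the glycolysis and hypoxia, immediate early, amino acid response and mitotic lists, some genes fell in knockout and none rose. Of 31 glycolysis and hypoxia genes none rose and 17 fell (4 and 19 adjusted over the list alone), with a median log2 change of -0.62 and a camera adjusted p of 0.000371 (adjusted p 0.769 with an estimated correlation). BNIP3, a mitophagy receptor, fell from 94.7 ± 25.9 to 8.64 ± 1.84 CPM (SD, n = 2 and 3), VEGFA, an angiogenic factor, from 33.4 ± 18.5 to 3.23 ± 0.0206, P4HA1 from 180 ± 5.25 to 59.8 ± 2.32 and DDIT4, an inhibitor of mTORC1, from 56.6 ± 17.5 to 7.11 ± 1.17 CPM (adjusted p 0.00218 to 0.00287). Of 25 immediate early genes none rose and 9 fell (0 and 9 adjusted over the list alone; median -0.86, camera adjusted p 0.00760, and 0.769 with an estimated correlation), with IER3 falling from 25.2 ± 4.75 to 7.98 ± 1.33 and FOS from 6.51 ± 0.211 to 1.58 ± 0.374 CPM. Of 30 amino acid response and unfolded protein genes none rose and 11 fell (0 and 11 adjusted over the list alone; median -0.60, camera adjusted p 0.0188, and 0.781 with an estimated correlation). DDIT3, a transcription factor of the integrated stress response, fell from 32.3 ± 6.58 to 5.30 ± 0.383 CPM, VLDLR from 52.6 to 11.7 and MTHFD2, a mitochondrial folate enzyme, from 353 to 171 CPM. That list was lost without wild type 1 (median -0.14, adjusted p 0.0972). Of 35 mitotic genes none rose and 9 fell (0 and 8 adjusted over the list alone; median -0.43, camera adjusted p 0.0210, and 0.812 with an estimated correlation). PLK1 fell from 154 ± 37.0 to 88.8 ± 6.42 CPM and KIF20A from 144 ± 47.6 to 81.9 ± 6.46 CPM. Without wild type 2 the mitotic median was 0.03 (adjusted p 0.905), and the list was lost without knockout 1 (0.0612) and with no filter on low counts (0.0619). PLK1 was lost without knockout 1, 2 or 3 (adjusted p 0.0547, 0.0538 and 0.0647), as was KIF20A (0.0922, 0.0772 and 0.0796), and without wild type 2 their log2 changes were -0.50 and -0.40 instead of -0.79 and -0.81. With an estimated correlation between genes, 0 of the 8 called lists held (the 7 named here and in the paragraph on ribosome genes, and the B-lineage markers), with adjusted p values of 0.769 to 0.812. Among the called lists the estimated correlation was near the preset 0.01 only for glycolysis and hypoxia genes (0.0134). For the others it ran from 0.0893 (immediate early) to 0.841 (mitotic), with 0.363 for DNA replication and 0.235 for ribosome biogenesis. The camera p values of those lists at the preset assume a far lower correlation and may be too small. For glycolysis and hypoxia genes the unadjusted camera p still rose from 3.97e-05 to 0.0288. The loss of that list thus does not measure correlation alone.

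Markers of other blood lineages were mostly low and fell where they changed. Of 5 B-lineage markers 3 fell (3 adjusted over the list alone; median -2.18, camera adjusted p 0.0322, and 0.769 with an estimated correlation): BLNK, VPREB3 (0.241 to 0.0529 CPM) and IGLL1 (0.313 to 0.0574 CPM). That list was lost without wild type 1 (adjusted p 0.192), without knockout 2 (0.0849), with upper-quartile scaling (0.0761), with no filter (0.0734) and with a minimum of 1 CPM (0.140). VPREB3 was lost without wild type 1, wild type 2, knockout 2 or knockout 3 (adjusted p 0.0913, 0.104, 0.0859 and 0.0858) and IGLL1 without wild type 1 or knockout 1 (0.220 and 0.0850). Of 4 myeloid markers 2 fell (2 adjusted over the list alone; camera adjusted p 0.368), CD68 and ITGAM, the latter from 14.4 ± 6.73 to 0.787 ± 0.423 CPM (SD, n = 2 and 3, adjusted p 0.00415). Of 4 erythroid and megakaryocyte markers 3 fell (3 adjusted over the list alone; camera adjusted p 0.0940): KLF1 (0.866 to 0.254 CPM), EPOR (10.7 to 6.17) and ITGA2B (0.796 to 0.196). Each was lost in 4 of the 5 fits that left out 1 library, KLF1 without wild type 1 or knockout 1, 2 or 3 (adjusted p 0.112, 0.0732, 0.0646 and 0.0868), EPOR without the same libraries (0.0679, 0.0887, 0.0749 and 0.0984), and ITGA2B without wild type 1, wild type 2, knockout 1 or knockout 3 (0.0766, 0.0657, 0.0881 and 0.112). Of 6 natural killer cell markers 0 were called (0 adjusted over the list alone; camera adjusted p 0.955), and NCAM1 had 14.7 CPM in wild type and 13.6 CPM in knockout. Of 7 stromal and epithelial markers 2 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p 0.414), with KRT8 falling from 3.31 to 0.143 CPM (adjusted p 0.00299).

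In the other lists single genes changed without a camera call for the list. Of 25 end joining and PARP genes 7 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p 0.341). SHLD2, a shieldin subunit, rose from 45.8 to 82.4 CPM, and XRCC6 (Ku70) from 512 to 950 CPM, the latter lost without knockout 2 or 3 (adjusted p 0.0558 and 0.0569). Of 27 p53 targets 2 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p 0.565). GADD45B fell from 22.2 ± 0.945 to 5.96 ± 0.862 CPM (SD, n = 2 and 3), TP53INP1 from 58.1 to 17.7 and CCNG1 from 336 to 143, while AEN rose from 17.4 to 57.5 CPM. Of 41 interferon-stimulated genes 8 rose and 7 fell (8 and 8 adjusted over the list alone; camera adjusted p 0.936), among them EPSTI1, which fell from 268 ± 24.4 to 58.6 ± 12.01 CPM, and HERC6, which rose from 3.79 to 10.4 CPM. Of 18 MHC genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p 0.673). TAPBP, which encodes tapasin, rose from 92.7 to 162 CPM, and HLA-E fell from 184 to 60.3 CPM with a call lost without knockout 1 (adjusted p 0.0504) and a log2 change of -0.98 instead of -1.61 without wild type 1. Of 29 JAK-STAT genes 2 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p 0.375), with STAT5B falling from 399 ± 27.7 to 153 ± 10.4 CPM and STAT5A from 153 ± 7.04 to 56.1 ± 11.6 CPM, a pair of paralogues that share reads.

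The BCL2 family of 14 genes had 3 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p 0.556), with a mean of -0.16 against a median of 0.20 and an upward test. BID, which links caspase 8 to the mitochondria, rose from 22.3 to 45.8 CPM (adjusted p 0.00585), and BCL2 fell from 72.3 to 39.7 CPM with a call lost without wild type 1 or knockout 3 (adjusted p 0.0619 and 0.0634). Of 24 clustered protocadherins 1 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p 0.375). These were PCDHB13 (0.787 to 2.87 CPM), lost without wild type 1, knockout 2 or knockout 3 (adjusted p 0.0822, 0.0906 and 0.0849), and PCDHGA1 (0.431 to 0.0674 CPM), lost without wild type 1 or knockout 1, 2 or 3 (0.219, 0.0708, 0.0770 and 0.0853). Of 28 sterol and fatty acid synthesis genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p 0.569). FASN, the fatty acid synthase, rose from 94.9 to 168 CPM (adjusted p 0.00776), and FADS2, a fatty acid desaturase, rose from 229 to 378 CPM with a call lost without knockout 2 or 3 (adjusted p 0.0598 and 0.0569). The cohesin list had an upward test (camera adjusted p 0.997) with a negative median and mean (-0.04 and -0.15).

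**Figure D2:**
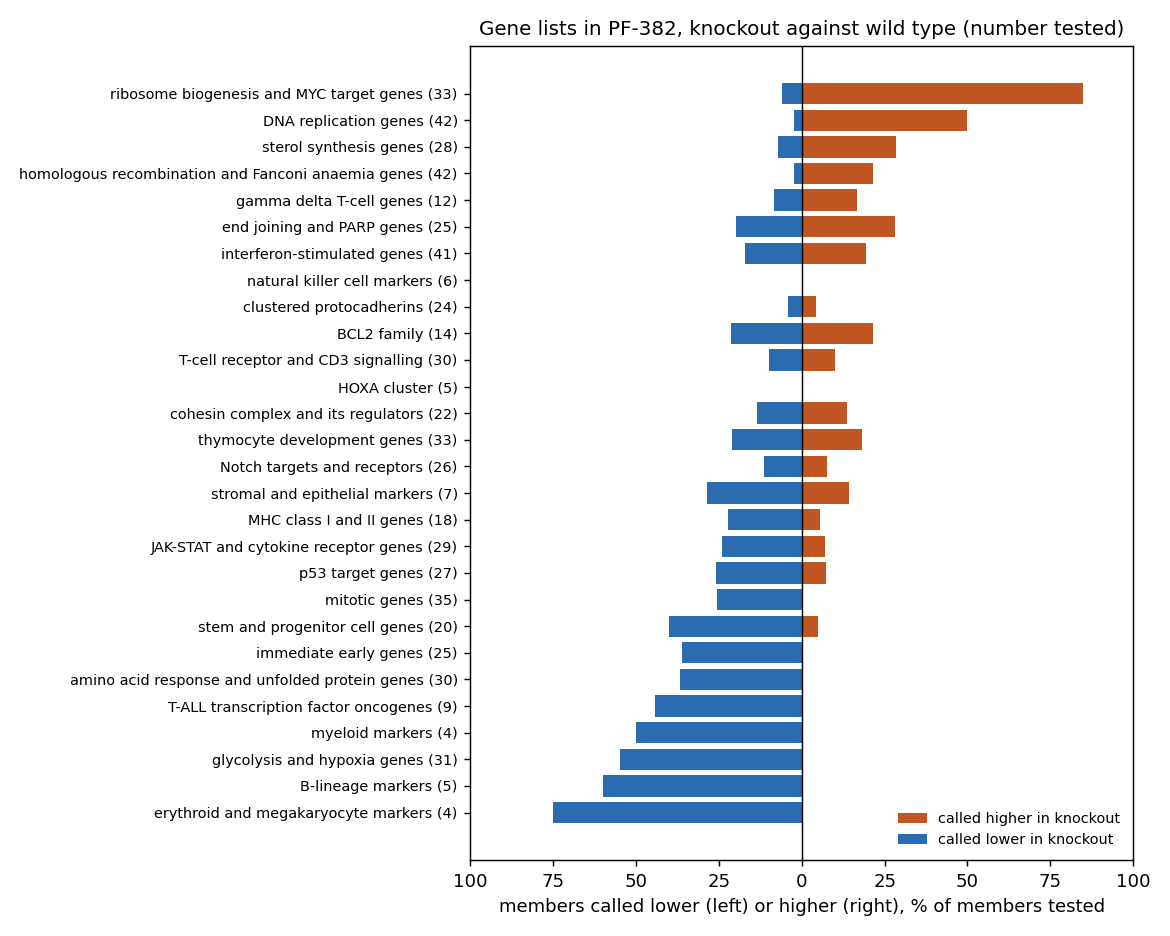
Share of the tested members of each of the 28 gene lists that were called higher (right) or lower (left) in PF-382 knockout against wild type, in percent, with the number tested in brackets. Ribosome biogenesis genes stood at the top with 28 of 33 higher, and 17 of 31 glycolysis and hypoxia genes were lower.

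In MOLT-14 the comparison asks which genes differ when STAG2 is added, and with 1 library per group it gives values and no test. STAG2 had 56 counts (1.35 CPM) with the empty vector and 6878 counts (164 CPM) with STAG2, a 121-fold ratio (95% interval 93.0 to 160, counting error only). STAG1 had 125 and 130 CPM, RAD21 574 and 741 CPM, and LMO2 32.5 and 35.3 CPM (log2 ratio 0.12). Of 11442 genes with at least 5 CPM in either library, 134 were at least 2-fold higher and 88 at least 2-fold lower with STAG2. With no scaling beyond the library total, which moved the median log2 ratio of all genes from 0.05 to -0.15, the counts were 69 and 180. Among protein-coding genes with at least 5 CPM in either library, the highest ratios after that of STAG2 were those of CYP4F2 (7.59-fold), LGALS12 (6.10-fold, 5.605 to 34.2 CPM), IL32 (4.63-fold, 3.82 to 17.7 CPM), EPHA4 (3.79-fold), GIMAP7 (3.72-fold), SH3BP5 (3.66-fold, 38.2 to 139.8 CPM), ADARB2 (3.59-fold), CTSH (3.41-fold) and TIE1 (3.31-fold). Of these protein-coding genes CD163L1 was lowest, with 310 counts against 2, a ratio of 157-fold lower (95% interval 43.2 to 1306). The next protein-coding genes were LY75 (9.18-fold lower), CR1 (7.37-fold), DNAH5 (5.63-fold), VCAN (4.99-fold), ISM1 (4.26-fold), ATF5 (4.09-fold, 135.8 to 33.2 CPM), LGALS1 (4.02-fold), GADD45G (3.85-fold) and TNFRSF19 (3.62-fold).

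Cell-cycle genes lay higher in the MOLT-14 library with STAG2. The median log2 ratio was 0.60 for 35 mitotic genes, 0.31 for 42 DNA replication genes, 0.27 for 20 cohesin genes, STAG2 included, and 0.24 for 27 sterol genes, each above the central 95% of 10000 random lists matched on expression. Below that range lay p53 targets (-0.20), immediate early genes (-0.24), amino acid response genes (-0.22), ribosome biogenesis genes (-0.01, random range 0.01 to 0.21) and 3 myeloid markers (-0.51). These were 9 of the 26 lists compared. The random lists hold unrelated genes, so a list whose genes move together can leave this range through a small difference between the libraries. Inside the range lay the T-ALL oncogenes (0.15), stem genes (0.12), T-cell receptor genes (0.20), thymocyte genes (0.22), gamma delta genes (0.20), Notch genes (0.09), homologous recombination genes (0.10), end joining genes (0.09), interferon-stimulated genes (0.07), MHC genes (0.13), JAK-STAT genes (0.07), the BCL2 family (-0.02), protocadherins (-0.16), glycolysis and hypoxia genes (0.08), and the B-lineage (0.39), natural killer (0.15) and stromal (0.04) markers. The B-lineage list held 2 genes here, and the natural killer and stromal lists 3 each. The HOXA and the erythroid and megakaryocyte lists had too few genes above 5 CPM to be compared. Mitochondrial genes took 4.92% of the counts with the empty vector and 1.43% with STAG2. Of the genes with the largest changes in PF-382, CD68 had 97 counts with the empty vector and 10 with STAG2 (9.86-fold lower), ZNF697 was 2.36-fold lower, CD8B had 66 and 47 counts, and HSPA6 50 and 43. CTSG (16.0 and 16.2 CPM), CRISPLD1 (16.5 and 19.2), BHLHE40 (6.79 and 6.13) and CTBP2 (68.8 and 82.7) differed by less than 1.5 times, and MT1H, ANXA3 and SMC1B had 0 counts in both libraries.

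Across both lines, an effect of STAG2 that the lines share would have opposite signs, since STAG2 is knocked out in PF-382 and added in MOLT-14. STAG2 RNA changed by -1.13 on the log2 scale in knockout, so part of it remained, and the protein was not measured here. The 10 genes named by rule, which fell in PF-382 knockout, lay at least 2-fold higher in MOLT-14 with STAG2. TEX19 changed by -1.86 ± 0.18 (SE) on the log2 scale in PF-382 and had 36.9 CPM with the empty vector and 78.8 CPM with STAG2 in MOLT-14. RGS12, a regulator of G-protein signalling, changed by -2.60 with 10.9 and 26.1 CPM in MOLT-14, GIMAP1, a GTPase of lymphocytes, by -2.80 with 12.2 and 32.5 CPM, and LGALS9, which encodes galectin-9, by -0.98 with 25.6 and 60.0 CPM. LINC01749, ERVFRD-1, PAX6, COL2A1, AC005336.3 and SCARNA12 completed this set, with PF-382 changes from -6.48 (COL2A1) to -0.76 (SCARNA12) and adjusted p values of 0.00218 to 0.00537 over the set. In all, 72 called genes, the altered gene STAG2 among them, lay at least 2-fold the opposite way in MOLT-14 and 75 the same way. Of these, 21 of the 72 and 4 of the 75 were small RNA genes, and the 21 were all lower in PF-382 knockout. Small RNA genes took 4.87% of the counts in MOLT-14 with the empty vector and 9.27% with STAG2, 1 library each. In PF-382 they took 21.0% and 14.9% in wild type and 11.96% to 13.98% in knockout. Their share was thus higher with more STAG2 RNA in both lines, but wild type 2 and knockout 2 lay close together. RN7SK alone took 7.58% to 8.18% in wild type and 5.41% to 6.13% in knockout, and a link with STAG2 was not tested. Of the genes higher in PF-382 knockout, 1046 of 2624 (39.9%, exact 95% interval 38.0 to 41.8) had the opposite sign in MOLT-14, at percentile 17.9 of random gene sets matched on expression (central 95% 38.9% to 42.6%). Of those lower in knockout, 974 of 1888 (51.6%, 49.3 to 53.9) had the opposite sign, at percentile 90.4 (48.0% to 52.3%). The intervals and the random sets treat genes as independent, which they are not. They cover no spread between libraries and are likely too narrow. Among genes called with at least 2-fold changes the shares were 48.3% in both directions. These lay above the 44.7% (higher) and 45.2% (lower) of random sets, at percentiles 98.9 and 98.2. The lower set holds STAG2 itself and small RNA genes, and their part in this excess was not tested. Across 13982 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.02 and Spearman's rho 0.05.

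**Figure D3:**
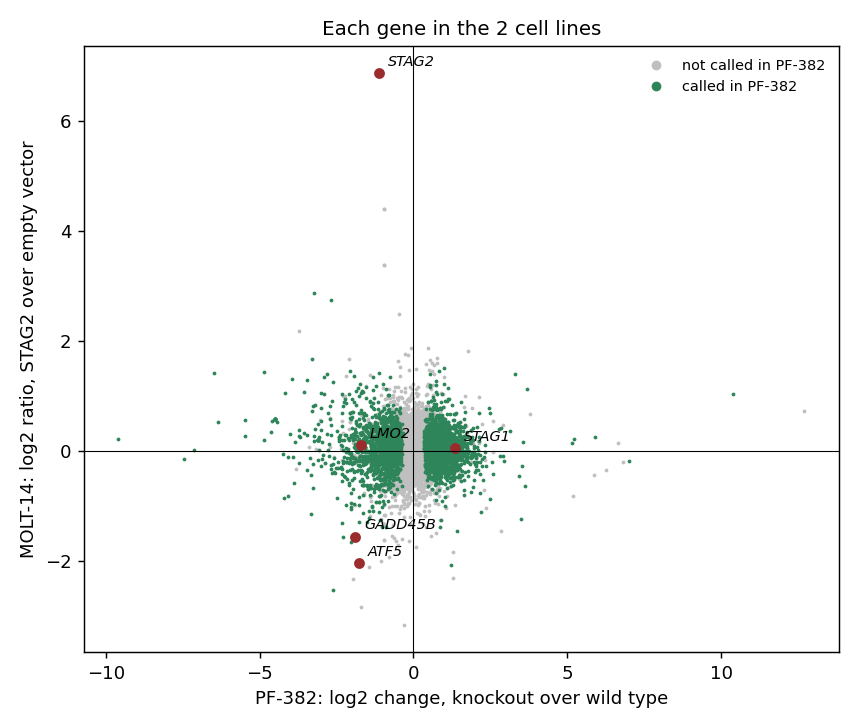
Log2 change in PF-382 (knockout over wild type, horizontal) against log2 ratio in MOLT-14 (STAG2 over empty vector, vertical) for 11190 genes, 1 point per gene, with the 3829 genes called in PF-382 in green. STAG2 lies at -1.13 and 6.87, STAG1 at 1.36 and 0.06, and LMO2 at -1.72 and 0.12.

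A fit of all 7 libraries with the cell line as a term gave 1 average change with STAG2 status over both lines, which does not require a gene to move in each. LMO2 changed by -1.24 ± 0.34 (SE) on the log2 scale with low STAG2 and did not pass (adjusted p 0.129; 3 knockout and 1 empty-vector libraries against 2 wild-type and 1 STAG2 libraries). STAG2 itself did not pass (adjusted p 0.212). Of 20100 genes edgeR called 0, with 4654 at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. DESeq2's Wald test on the same design called 2097 genes, 1009 higher and 1088 lower with low STAG2, among them LMO2 (adjusted p 0.00908). LMO2 had 27.6 CPM with the empty vector and 29.6 CPM with STAG2 in MOLT-14, so its change in this fit comes from PF-382. The edgeR count was 409 with no filter on low counts, 1 without wild type 1 and 2 without knockout 1.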

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

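Of the tests below, thinning and the GC and length trend were set down before their results were seen, and the tests of culture state, shared reads, copy number and MOLT-14 levels afterwards. The thinning and trend settings themselves were chosen after seeing the data.

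Genes and lists that went the same way in both lines were picked out because STAG2 falls in 1 comparison and is added in the other. ATF5, a transcription factor of the stress response, changed by -1.77 on the log2 scale in PF-382 knockout and had a ratio of -2.03 in MOLT-14 with STAG2. GADD45B changed by -1.90 in PF-382 with a MOLT-14 ratio of -1.55. MT-ND4, a mitochondrially encoded subunit of complex I, changed by -2.01 with a ratio of -1.003. TMEM189-UBE2V1 rose from 0 counts in PF-382 and had a ratio of 1.04 in MOLT-14. These are named genes with at least 5 CPM in either MOLT-14 library. CD68, below that level, went the same way too, with -6.32 in PF-382 and -3.07 in MOLT-14. Other named genes went opposite ways by at least 2-fold in both lines. Besides STAG2 they included CYP4F2 (-3.22 and 2.87), ZNF697 (3.51 and -1.22) and ISM1 (1.22 and -2.07). Of all genes called in PF-382, 75 lay at least 2-fold the same way in MOLT-14 and 72 the opposite way. The genes named here are thus a pick from 1 side of near-equal counts. DNA replication genes had medians of 0.73 in PF-382 and 0.31 in MOLT-14, immediate early genes -0.86 and -0.24, and amino acid response genes -0.60 and -0.22. Homologous recombination genes had medians of the same sign too, 0.32 and 0.10, the latter inside the range of random lists in MOLT-14. The 4 other lists called in PF-382 had medians of opposite sign. Mitotic genes had -0.43 and 0.60 and ribosome biogenesis genes 1.16 and -0.01, both outside that range in MOLT-14. Glycolysis and hypoxia genes had -0.62 and 0.08 and B-lineage markers -2.18 and 0.39, both inside it. The B-lineage median in MOLT-14 rests on 2 genes, and BLNK, with 1 count in each library, is not among them. The PF-382 calls of these 8 lists were lost with an estimated correlation (adjusted p 0.769 to 0.812), and the mitotic list was also lost without wild type 2 (median 0.03, adjusted p 0.905). Of the lists added after seeing the data, histone genes (0.81 and 0.67) and mitochondrially encoded genes (-0.55 and -0.95) also went the same way. Ribosomal protein genes (-0.37 and 0.41) went opposite ways. The differences between lines were not tested, since MOLT-14 has 1 library per group.

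The first pattern is the breadth of the PF-382 change, 5311 of 17442 genes. Depth as its whole cause is argued against by thinning every library to the smallest total, after which at least 84.8% of the calls were made again in the same direction in each of 5 draws. A trend on GC content and gene length is argued against likewise, with 88.3% of the calls made again after its removal. The state of the wild-type cultures cannot be told apart from the genotype, because both wild-type libraries make up the group, and the 17 glycolysis and hypoxia genes lower in knockout are what either may give. The loss of STAG2 stays open beside it, untested against culture state.

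The second pattern is the rise of STAG1. Reads shared with STAG2 would lower STAG1 where STAG2 falls, and its log2 change of 1.36 ± 0.11 (SE) runs the other way. That change is the pattern itself, so the outcome of this test was known in advance. A gain of its region is argued against by a median log2 change of -0.17 ± 0.16 (SE) over 24 genes within 2 Mb. Whether STAG1 follows the level of STAG2 in other cells cannot be told from MOLT-14, where its log2 ratio was 0.0637 with 1 library per group. A response of STAG1 to the loss of STAG2 may account for the rise, and so may the state of the wild-type cultures, which was not tested for STAG1.

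The third pattern is the fall of LMO2. A loss of its region is argued against by a median log2 change of 0.50 ± 0.19 (SE) over 25 genes within 2 Mb, of which 5 rose and 1 fell. Depth is argued against by a log2 change of -1.77 ± 0.29 (SE) after thinning, in the first of 5 draws. The MOLT-14 log2 ratio of 0.12 decides nothing, with 1 library per group. The state of the wild-type cultures stays open for LMO2 as for other genes, and no test separates it from the loss of STAG2.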

How the results depend on the processing

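Thinning, the protein-coding subset and the trend removal were chosen after seeing the data. No gene called in PF-382 was called in the opposite direction in any of the 19 alternative fits, and of 140 named genes called, 42 were called in each of them. DESeq2's size factors, DESeq2's test, voom, robust dispersion, unrounded counts, both filters, all 7 libraries in 1 fit, thinning, protein-coding genes only and trend removal gave 3984 to 6334 called genes, of which 4080 to 5300 were among the 5311 outside the protein-coding subset (86.0% of protein-coding calls there). Upper-quartile scaling gave 1824 higher, by moving the median of all genes. Leaving out 1 library gave 2271 to 6304 genes (1194 to 3570 higher, 1077 to 2734 lower), with the low counts in the fits with 2 knockout libraries. The libraries with SA titles gave 306 genes (114 higher, 192 lower), with 1 knockout library, and the SB knockout libraries 2649 (1405 and 1244), the fit without knockout 1. The number of lists called was 6 to 8 under the scaling and filter alternatives, 5 to 9 without 1 library and 0 with an estimated correlation. The median of the mitotic list ranged from -0.78 to 0.0292 without 1 library, turning upward without wild type 2, and the cause was not tested. In MOLT-14, no scaling gave 69 higher and 180 lower, a minimum of 1 CPM gave 290 and 303 by comparing more genes, and a minimum of 10 CPM gave 50 lower by comparing fewer. The opposite-sign shares were 48.3% (higher) and 48.3% (lower) for genes changed at least 2-fold, 36.5% (higher) with DESeq2's size factors, 56.5% (lower) with at least 5 CPM in MOLT-14, and 39.2% to 42.0% (higher) and 51.3% to 54.0% (lower) without 1 library. The cause was not tested. The shared fit gave 0 genes with edgeR and DESeq2's size factors, 2097 with DESeq2's test, 409 with no filter and 0 to 2 without 1 library, and the cause was not tested. Depth sets a floor of 0.0319 to 0.0920 CPM for 3 counts, and BLNK, ADM, BHLHE40 and MT1H lay around or under it in knockout.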

Other observations

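Several gene families outside the lists fixed beforehand were tested in PF-382. They were picked because members stood among the changed genes, so their counts are not independent evidence. Of 63 replication-dependent histone genes 44 rose and 1 fell in knockout (median log2 change 0.81), with HIST1H3A rising from 51.2 ± 4.56 CPM (SD, n = 2) to 134 ± 8.39 CPM (SD, n = 3). Of 8 chaperonin genes, which fold actin and tubulin, 6 rose, with CCT3 rising from 251 ± 18.0 to 583 ± 20.04 CPM. Of 14 SR splicing factors 8 rose, 1 fell and 5 did not pass, with SRSF1 rising from 257 ± 2.78 to 742 ± 26.0 CPM. Of 81 cytosolic ribosomal protein genes 3 rose, 21 fell and 57 did not pass (median -0.37), and RPS26 rose from 68.9 to 193 CPM. Camera adjusted over these lists gave p values of 4.03e-14 (histones), 0.000685 (chaperonins), 0.00169 (SR factors) and 4.98e-06 (ribosomal proteins), and with an estimated correlation 0 of the 7 lists held (adjusted p 0.467 to 0.977).

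Some inducible HSP70 genes, most metallothionein genes tested and 6 of 13 mitochondrially encoded genes fell in PF-382 knockout. HSPA1B fell from 784 ± 269 CPM (SD, n = 2) to 53.3 ± 4.91 CPM (SD, n = 3) and HSPA1A, a near-identical paralogue that shares its reads, from 533 ± 202 to 34.9 ± 21.9 CPM. Of 22 heat shock genes 7 fell and 9 rose (camera adjusted p 0.916), the latter with AHSA1, a cofactor of HSP90, from 59.6 to 101 CPM. Of 6 metallothionein genes 5 fell (camera adjusted p 0.00684, and 0.467 with an estimated correlation), with MT1E falling from 5.65 ± 0.218 to 0.279 ± 0.149 CPM. Of 13 mitochondrially encoded protein genes 6 fell (camera adjusted p 0.0152, and 0.476 with an estimated correlation), with MT-CO1 falling from 2346 to 955 CPM and MT-ND4 from 151 to 37.4 CPM. Mitochondrial genes took 0.5998% and 0.550% of the counts in the wild-type libraries and 0.322%, 0.256% and 0.222% in the knockout libraries.

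RAG1, a recombinase of antigen receptor genes, was chosen after its values were seen. With the 7 libraries scaled together it had 54.0 and 4.69 CPM in the wild-type libraries and 204, 167 and 332 CPM in the knockout libraries, and it did not pass in PF-382 (adjusted p 0.0566). RAG2 had 6.17 and 0.415 CPM in wild type and 5.84, 7.55 and 16.6 CPM in knockout. TRBV20-1 had 733.7 to 1258 CPM in the PF-382 libraries and 0 counts in MOLT-14, where TRBC1 had 633 and 737 CPM and TRDC 62.4 and 59.0 CPM. TRBC1 had at most 0.163 CPM in PF-382.

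The length of STAG2 implied by counts over TPM, relative to GAPDH, was 1.95 in the MOLT-14 library with STAG2, 3.97 to 4.20 in the PF-382 libraries and 0.813 on the 56 counts of the empty-vector library. The median log2 level of 137 genes on chromosome 18 was -0.29 in knockout 2 against the other knockout libraries, while the other autosomes lay between -0.11 and 0.08 in every knockout library.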
